A study of Homo sapiens with 8 samples.

How the data were processed

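Total RNA from Huh7 cells, an established human hepatoma line, was measured on 8 one-colour (Cy3) Agilent gene expression arrays. Per the labels' protocols, cells were seeded in medium without antibiotics, transfected 24 h later and harvested 48 h after transfection, and cRNA was prepared from 0.1 ug of RNA per sample. The titles put 4 samples in the control group (replicates 1, 2, 7 and 8). The other 4 (replicates 3, 4, 9 and 10) carry a label read here as the miR-342-3p mimic, because the series names only a scramble control and that mimic. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

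The deposited scanner files hold spot intensity values on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5. Per the file headers, the processed intensity of a spot is background-subtracted and spatially detrended, and it is not scaled between arrays. The deposited files also carry spot flags set by Feature Extraction, used here for control spots, outliers, saturation and signal well above background. The deposited series matrix holds log2 values with scale and centring unstated. Set against each array's log2 median spot intensity, its columns correlated at 0.998 to 1.000 across probes, with slopes of 0.990 to 1.03 and column medians of 6.93 to 6.95, so they were taken as log2 median intensities brought to a shared distribution, without background subtraction. What remains unknown is the exact between-array method. That table served only as an alternative. The file headers place each array on a slide: replicates 1 to 4 shared slide 1 and replicates 7 to 10 shared slide 2, and on each slide the controls lay at positions 1 and 2 and the mimic arrays at positions 3 and 4.

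From the deposited intensities, log2 of the processed signal was averaged over spots of a probe, without control spots and spots with an outlier flag, and each array's 75th percentile over non-control probes was subtracted. All levels below are log2 signals relative to that percentile. Probes were named through their RefSeq accession, without versions on both sides, in a RefSeq gene table of another genome build than the array's design, so no coordinates are given: 25771 of 34127 probes reached 19740 gene symbols and 8356 probes stayed unnamed (RefSeq table of GRCh38.p14). A probe was tested when it was well above background on at least 3 of the 4 arrays of a group. The brightest tested probe stood for the gene, which left 13974 genes, 3405 of them with more than 1 tested probe. No spot was saturated. The number of arrays limits the precision.

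Mimic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group only, Benjamini-Hochberg over genes, threshold 0.05). Because each slide held both groups, the same fit with slide as a fixed block and the change within each slide were computed as well. In all, 36 gene lists with 959 genes (849 measured) were fixed before the data were examined and tested with limma's camera (preset correlation 0.01, against all other tested genes, Benjamini-Hochberg over lists), with camera under an estimated correlation, and with fry, which tests whether a list's genes move, on balance, one way and compares them with no other genes. Camera and fry used genes without a missing value, which left out 20 genes. For single values per array, exact permutation tests over the 70 assignments of 4 and 4 arrays were used. Their smallest possible two-sided p is 0.0286.

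Genes were named by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls past the threshold among probes well above background on all 8 arrays whose 4 mimic values all lay on one side of the 4 control values and whose name is a gene symbol (not an open reading frame, locus or probe name), every measured reported target of miR-342-3p, from each list up to 4 members past the threshold or up to 2 with the largest change where none passed, genes above background in 1 group only, and EVL, the host gene of the microRNA. The same rule was also applied to the fit with slide as a block, a step chosen after the values were seen. Of the genes these rules name, 4 are not reported here. Genes above background in 1 group only were named from that fit alone, since none passed the group-only one. Their fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

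Alternatives covered normexp background correction (offset 50, on the median spot and background signals, since no mean signal was used here), quantile normalization, median centring, the filter on dim probes, outlier spots, the mean of probes, variance models (statmod 1.5.0 for the robust one), the series matrix, each slide alone, stricter thresholds and leaving out each array. The planned test of genes with a seed site for the microRNA needs transcript sequences, which were not used here. On simulated data drawn from the real genes' means, slide differences and spreads (10 draws of 200 changed genes among 13954), the group-only fit recovered 18.6% of genes changed by 0.5 on the log2 scale, 73.8% of those changed by 1, 88.8% of those changed by 1.5 and 92.8% of those changed by 2, with 0.2 false calls per draw. With slide as a block the shares were 71.4%, 95.0%, 99.2% and 99.2%, with 10.9 false calls per draw. The simulated noise was independent between genes, and 50 genes were changed by each size. In the real data 9 genes called with slide as a block exceeded 2-fold. The shares and false calls therefore need not hold for the real data.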

Results

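The series asked how a mimic of miR-342-3p, described in its labels as a tumour suppressor microRNA, alters gene expression in Huh7 hepatoma cells. Expression was profiled 48 h after transfection on 4 arrays of cells that received a scramble control and 4 arrays of cells that received the mimic. The 75th percentile of processed intensity ranged from 888 in control replicate 1 to 1517 in mimic replicate 9. Between 59.3% and 73.1% of probes were well above background, with 59.3% to 63.4% on slide 1 and 67.4% to 73.1% on slide 2. The arrays separated first by slide: the first principal component held 64.5% of the variance and parted slide 1 from slide 2, and the second held 14.0% and parted mimic from control arrays within each slide. Pearson correlations across genes were 0.990 to 0.998 within a slide and 0.976 to 0.988 between slides. With slide as a term in limma, 6798 of 13974 genes (48.6%) differed between slides at an adjusted p under 0.05. Replicate pairs on a slide differed by a median of 0.09 to 0.12 on the log2 scale, and no spot held identical values in both arrays of a pair.

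**Figure D1:**
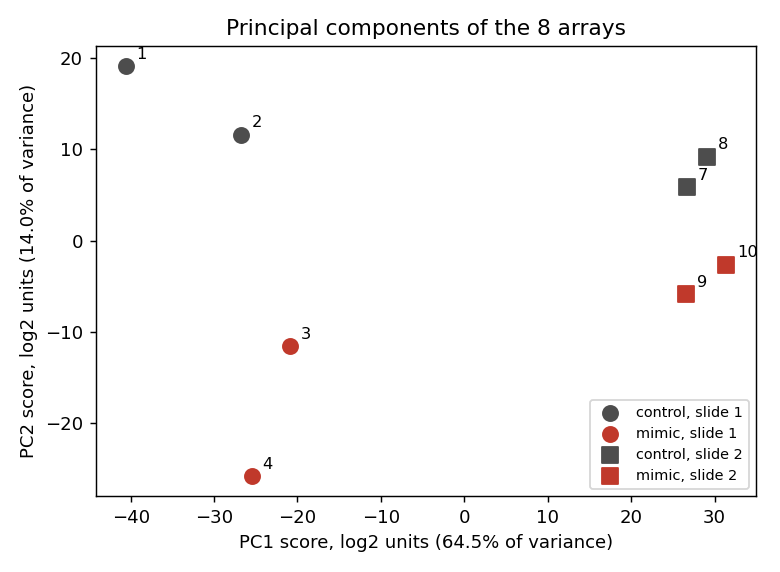
Scores of the 8 arrays on the first (x axis) and second (y axis) principal component, in log2 units, over genes without missing values; colour gives the group, symbol shape the slide, and the number the replicate. Slide 1 arrays lie on the left and slide 2 arrays on the right (64.5% of the variance), and mimic arrays lie below control arrays on the second component (14.0%).

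Mimic-transfected cells carried less mRNA of TACC1, TENT5C, PABIR2 and NACAD and more of IL1RAP, MIGA1 and SPOPL than control cells. TACC1, a coiled-coil protein linked to the centrosome, fell 2.62-fold from a control level of 3.88 ± 0.32 (log2 signal, SD, n = 4; log2 fold change -1.39 ± 0.15 SE, limma adjusted p = 0.0276). TENT5C, a poly(A) polymerase, fell 2.17-fold (log2 fold change -1.11 ± 0.11 SE, adjusted p = 0.0247). IL1RAP, the accessory chain of the interleukin-1 receptor, rose 2.22-fold, from -0.57 ± 0.08 to 0.58 ± 0.25 (SD, n = 4 each; log2 fold change 1.15 ± 0.13 SE, adjusted p = 0.0276). MIGA1, a mitochondrial fusion factor, and SPOPL, an adaptor of cullin-3 ubiquitin ligases, rose 1.88-fold and 1.87-fold. PCYOX1L rose by 0.59 and DENND2D by 0.56 on the log2 scale. Further falls were found for the zinc finger genes ZNF322 (-0.96 on the log2 scale) and ZNF512B (-0.89), for SEC61G (-0.86), a subunit of the protein translocation channel of the endoplasmic reticulum, and for BBS2 (-0.81), part of the ciliary BBSome. DCP1A (-0.78), an mRNA decapping factor, KDM6B (-0.73), a histone H3 lysine demethylase, and RNF187 (-0.72) also fell. The naming rule required all 4 mimic arrays to lie on one side of all 4 control arrays, so that separation is no further support for these genes.

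These genes were part of 21 past the threshold in the group-only limma fit, 6 higher and 15 lower, among 13974 tested. The others were FOXQ1 and BMPR2, described with their lists, and C19orf12 (0.61), ABHD14A (-0.64) and TDG (-0.56). The naming rule left out C19orf12 for its open-reading-frame name and ABHD14A and TDG for falling outside the 12 largest falls, and all 3 were added after their values were seen, without a run of the alternatives. Over 21 alternative settings, each of the other 18 lost the call in 9 (TACC1) to 16 (BMPR2, PCYOX1L). PCYOX1L (0.52), DENND2D (0.41), KDM6B (-0.56) and NACAD (-0.74) did not pass with normexp (adjusted p = 0.153, 0.0849, 0.0696 and 0.0696) or with quantile normalization (0.0762 each). IL1RAP (0.71, adjusted p = 0.123) and PABIR2 (-0.64, 0.0807) did not pass with the mean of probes. At an unadjusted p under 0.05 there were 1234. Groups did not overlap for 925 genes (6.62%), where chance gives 2.86%. The lowest adjusted p was 0.0247, and leaving out any single array left at most 1 gene higher and 1 lower. For C19orf12 a second probe gave a log2 fold change of -0.03, for IL1RAP a second probe gave 0.28, and for PABIR2 2 other probes gave -0.73 and -0.18, while the second probes of ZNF322 (-0.81) and DCP1A (-0.81) were close to the first.

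**Figure D2:**
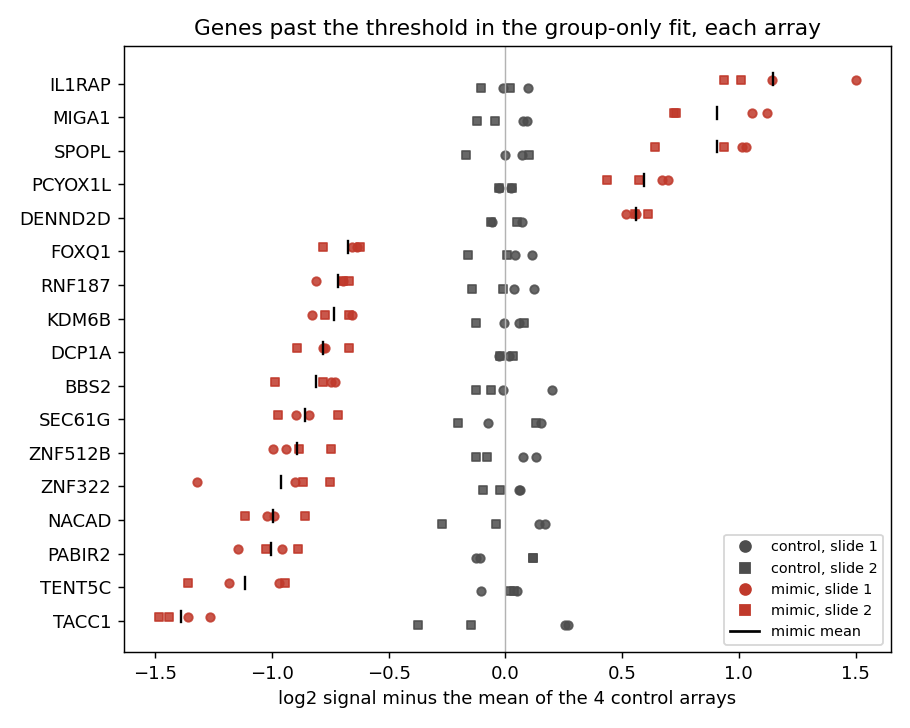
Log2 signal of each array minus the mean of the 4 control arrays (x axis) for the 17 genes named by the fixed rule as the largest rises and falls past the threshold (y axis). Grey is control, red is mimic, circles are slide 1, squares are slide 2, and black ticks are mimic means. TACC1 shows the largest fall (-1.39) and IL1RAP the largest rise (1.15). In each gene the mimic arrays stand apart from the control arrays, as the naming rule required.

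With slide as a block, 447 genes passed the threshold, 224 higher and 223 lower in mimic, including all 21 from the group-only fit. All 447 changed in the same direction on both slides, but the call itself used both slides, so this is no separate support. Their median absolute log2 fold change was 0.44, and 9 exceeded 2-fold. Leaving out any array other than control replicate 7 lowered both counts by over 1.5 times (34 higher and 72 lower without mimic replicate 9, 47 and 54 without mimic replicate 4), and without the filter on dim probes they were 11 and 21. Genes gained in this way included SQLE, which encodes squalene epoxidase of the cholesterol pathway (log2 fold change 1.01 ± 0.17 SE, adjusted p = 0.0223; 1.13 on slide 1 and 0.89 on slide 2), and IGFBP1, a secreted insulin-like growth factor binding protein (0.99 ± 0.06 SE, adjusted p = 0.00177; 1.02 and 0.95). ACVR1C, an activin receptor-like kinase, was higher by 0.94, the zinc finger gene ZNF91 by 0.90 and IL1RN, the interleukin-1 receptor antagonist, by 0.85, although a second probe of IL1RN gave -0.06. GLCE, IGIP, RBM24 and DORIP1 were higher by 0.75 to 0.79. With normexp, IGIP (0.25), RBM24 (0.19) and DORIP1 (0.21) did not pass with the block (adjusted p = 0.190, 0.306 and 0.210), and IL1RN was at 0.49. Among the genes lower with slide as a block were NRARP, a feedback regulator of Notch signalling (-1.07 ± 0.14 SE, adjusted p = 0.0141; -1.37 on slide 1 and -0.77 on slide 2), ERICH5 (-1.06), the adhesion molecule CADM1 (-1.07 on slide 1 and -0.93 on slide 2), the zinc transporter SLC30A2 (-0.99) and the planar polarity gene VANGL2 (-0.84). With normexp ERICH5 was at -0.58 and SLC30A2 at -0.51. None of SQLE, IGFBP1, ACVR1C, NRARP or CADM1 passed in the group-only fit, where their adjusted p lay between 0.108 and 0.243. TBX4, a T-box transcription factor, was well above background on all 4 control arrays and on no mimic array, at least 1.3-fold lower (adjusted p = 0.576, and 0.0164 with slide as a block, which normexp moved to 0.0781).

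Within slides, 2 arrays against 2, limma called 4 genes higher and 1 lower on slide 1 and 1 higher and 0 lower on slide 2. No gene showed a mimic effect that differed between slides past the threshold in a limma fit with an interaction term. At an unadjusted p under 0.05, 1373 of 13974 genes did. The 1234 genes for the mimic effect itself came from the group-only fit, where the slide difference stays in the spread. The 2 counts are therefore not comparable. With 2 arrays of a group on each slide, the lack of calls does not show that the effects were equal. The change on slide 1 and that on slide 2 correlated across genes with Pearson's r = 0.344 and Spearman's rho = 0.325; genes are not independent replicates.

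Of the 16 reported targets of miR-342-3p on the fixed list, 15 were measured, and 1, the forkhead transcription factor FOXQ1, fell in the group-only fit (-0.67 ± 0.09 SE, adjusted p = 0.0370), and did not pass with normexp (-0.61, adjusted p = 0.0594). SLC16A1, which encodes the lactate transporter MCT1, was at 0.34 ± 0.10 in control and -0.12 ± 0.10 in mimic arrays (SD, n = 4), a log2 fold change of -0.46 ± 0.09 SE with adjusted p = 0.115. With slide as a block SLC16A1 (adjusted p = 0.0251; -0.38 on slide 1 and -0.54 on slide 2) and the cell cycle transcription factor E2F1 (-0.34, adjusted p = 0.0383; -0.34 and -0.35) also fell. Adjusted over the list alone, 0 targets rose and 3 fell in the group-only fit, and 0 rose and 4 fell with the block. The other members had log2 fold changes of -0.32 for SOX6, -0.24 for RAP2B, -0.22 for ID4, -0.16 for FOXM1, -0.04 for SREBF2, -0.01 for IGF1R and IKBKG, 0.12 for TAB2 and SREBF1 (-0.19 and -0.14 from second probes), 0.17 for TAB3 and 0.18 for AGR2, all with adjusted p over 0.05 in both fits. DNMT1 stood at 0.67, from 1.33 on slide 1 and 0.01 on slide 2, with a control SD of 1.08 (n = 4). The list as a whole did not pass (mean log2 fold change -0.08, camera adjusted p = 0.0664; 0.281 with slide as a block), with means of 0.01 on slide 1 and -0.17 on slide 2. Without mimic replicate 10 its mean was -0.04, and it passed without mimic replicate 4 (-0.10, camera adjusted p = 0.0270), with the mean of probes (-0.10, 0.0241) and without the filter (-0.05, 0.0496). EVL, whose gene hosts the microRNA, was at 1.15 ± 0.21 in control and 1.03 ± 0.10 in mimic arrays (log2 fold change -0.12 ± 0.12 SE, adjusted p = 0.887).

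Cholesterol genes were higher in mimic arrays as a list. All 29 listed genes of cholesterol biosynthesis and uptake were measured, 24 had a positive and 5 a negative log2 fold change, and their mean was 0.20 (0.21 on slide 1, 0.19 on slide 2; camera adjusted p = 5.01e-07, and 1.53e-06 with slide as a block). With an estimated correlation the call was lost (adjusted p = 0.536, unadjusted p = 0.0298), and fry, which makes no comparison with other genes, gave an adjusted p of 0.108 without and 0.0157 with the block. No member passed alone in the group-only fit; adjusted over the list alone, 7 rose and 1 fell. With the block 5 rose and 1 fell over all genes, and 17 rose and 1 fell adjusted over the list alone. Beside SQLE, these included SC5D (0.41 ± 0.07 SE, adjusted p = 0.0276; 0.29 with normexp, not past the threshold), sterol-C5-desaturase. INSIG1, which retains the SREBP processing complex in the endoplasmic reticulum, moved the other way (-0.57 ± 0.12 SE, adjusted p = 0.0431; -0.41 on slide 1 and -0.73 on slide 2). The mean of the list was higher in all 4 mimic arrays than in any control array (exact permutation test of 4 against 4 arrays, two-sided, p = 0.0286, and 0.0556 within slides). Each p is the smallest possible and is not adjusted over the 36 lists.

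**Figure D3:**
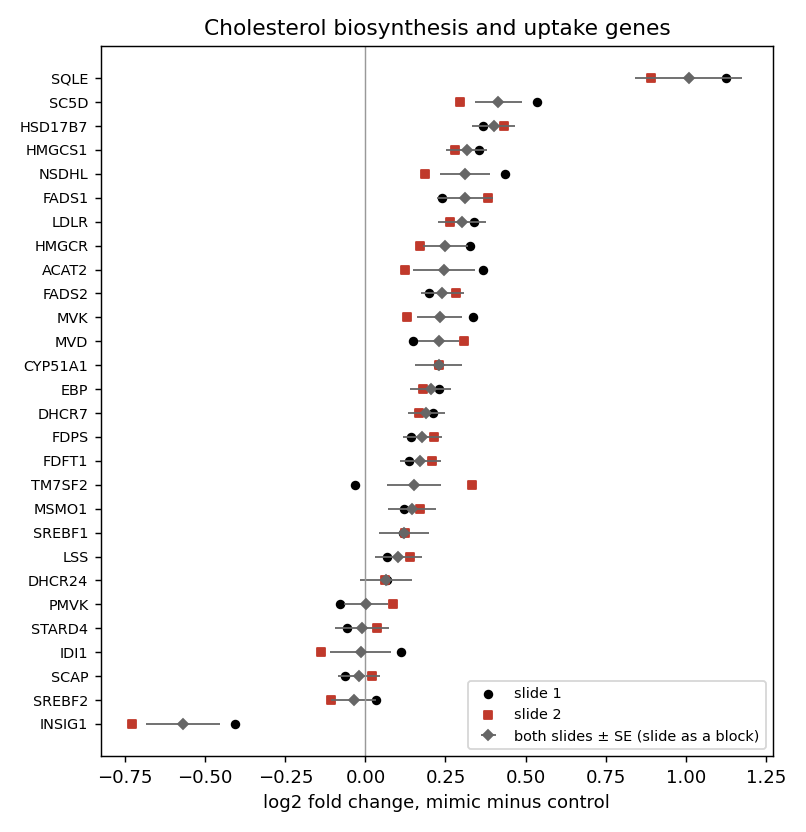
Log2 fold change, mimic minus control (x axis), of 28 of the 29 measured genes of the cholesterol list (y axis); diamonds with bars are both slides with the standard error of the slide-block fit, circles are slide 1 and squares are slide 2. SQLE (1.01) lies at the upper end, and INSIG1 (-0.57) is the lowest.

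The 24 measured genes of fatty acid synthesis and lipid storage also had a higher mean (0.13; 0.12 on slide 1, 0.14 on slide 2; camera adjusted p = 0.0135, and 0.00656 with the block). The group-only call was lost with an estimated correlation (adjusted p = 0.347), with array weights (0.0620), on slide 1 alone (0.225) and without mimic replicate 10 (0.0749). The block call was lost with an estimated correlation (0.610). Fry, which sets the list against no change and not against other genes, gave an adjusted p of 0.00985. Single members did not pass over all genes in either fit, and adjusted over the list alone 0 rose in the group-only fit and 6 rose and 1 fell with the block. ELOVL5, a fatty acid elongase, had a log2 fold change of 0.32 ± 0.22 SE, with -0.22 from a second probe, and ME1, malic enzyme, 0.31 ± 0.14 SE. The 23 genes of fatty acid oxidation and PPARA targets did not pass (mean 0.08, camera adjusted p = 0.312), and their largest values were 0.48 for FABP1 and 0.30 for PLIN2. Their list mean separated the groups (exact permutation test, two-sided, p = 0.0286, and 0.0556 within slides). Each p is the smallest possible and is not adjusted over the 36 lists.

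Among hepatocyte lists, secreted proteins had a mean log2 fold change of 0.12 over 44 genes (0.06 on slide 1, 0.19 on slide 2). The camera adjusted p was 0.0623 in the group-only fit and 0.0236 with slide as a block. The block call was lost with an estimated correlation (0.790), quantile normalization (0.0556) and without mimic replicates 3 or 9 (0.0580 and 0.143) or control replicates 7 or 8 (0.0978 and 0.170), and fry gave 0.261. Without the block the list passed in several alternatives, such as normexp (camera adjusted p = 0.00759), and its mean was 0.05 without mimic replicate 9. No member passed without the block (ITIH3 0.56, TF 0.44; adjusted over the list alone, 1 rose and 0 fell), and 5 rose with it, among them the fibrinogen chains FGG (0.40 ± 0.06 SE, adjusted p = 0.0184) and FGB (0.38), complement C5 (0.30) and the acute-phase gene ORM2 (0.28). Neither C5 nor ORM2 passed with quantile normalization, median centring or the mean of probes, and ORM2 did not with normexp or the series matrix. ASS1, argininosuccinate synthase, was the 1 gene of 29 hepatocyte enzymes and transporters that rose with the block (0.44, adjusted p = 0.0473; 0.21 from a second probe, and 0.32 with the mean of probes, not past the threshold). Of 25 liver transcription factors 3 rose with the block: PPARGC1A (0.44; 0.27 with normexp, not past the threshold), NR0B2 (0.36) and NR5A2 (0.33, with -0.06 from a second probe; not past the threshold with median centring or the mean of probes, 0.13). Neither list passed camera (adjusted p = 0.383 and 0.344). ARG1 (0.62) and ADH4 (-1.06) did not pass. ADH4 was well above background on 4 of 8 arrays. Oncofetal and progenitor markers had a mean of 0.00 over 21 genes (camera adjusted p = 0.990 with slide as a block), with EPCAM at -0.34 and PEG10 at 0.33.

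Proliferation lists did not pass in either fit. The means were -0.05 over 45 genes of G1/S and DNA replication (camera adjusted p = 0.299), -0.04 over 43 genes of G2/M and mitosis (0.378) and -0.11 over 21 G1 cyclins, CDKs and CDK inhibitors (0.0623). Alternatives to the group-only fit called the G1 cyclin list lower with array weights (-0.19, camera adjusted p = 0.00543), with the mean of probes (-0.13), without the filter (-0.09) and without mimic replicate 4 or control replicate 8 (-0.16 each). They called G2/M lower with weights (-0.09, camera adjusted p = 0.0206) and without mimic replicate 4 (-0.08). With the block G1/S passed as lower with quantile normalization, the series matrix, no filter or without mimic replicate 9 or control replicate 8. The G1 cyclin list did with the mean of probes or without mimic replicate 4 or control replicates 2 or 8. With the block POLA2, a DNA polymerase alpha subunit, fell (-0.49 ± 0.07 SE, adjusted p = 0.0162), as did E2F1. MKI67 (-0.31), BIRC5 (-0.29), CDKN2B (-0.44) and CDK4 (-0.30) did not pass in either fit. Of 23 p53 targets (mean -0.01, adjusted p = 0.848), SESN2 fell with the block (-0.44, adjusted p = 0.0185) and RRM2B stood at 0.35. The 26 BCL2 family and caspase genes had a mean of -0.05 (adjusted p = 0.690), with BIK at -1.04 ± 0.40 SE and XIAP at 0.30, neither past the threshold.

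Glycolysis and lactate genes (mean 0.05 over 28, camera adjusted p = 0.690) and hypoxia-inducible genes (0.10 over 26, 0.497) did not shift as lists, though the latter passed with array weights (0.20, camera adjusted p = 0.0339). With the block the glycolytic enzyme ENO2 fell (-0.43 ± 0.07 SE, adjusted p = 0.0201; -0.36 and 0.0551 with the series matrix), as did SLC16A1, and the collagen prolyl hydroxylase subunit P4HA2 fell (-0.60 ± 0.11 SE, adjusted p = 0.0334). STC2 stood at 0.48 with a control SD of 1.04 (n = 4). Oxidative phosphorylation genes had a mean of 0.03 over 47 (adjusted p = 0.690), with NDUFA6 at 0.47 and CYCS at 0.31 (-0.06 to 0.17 from other probes).

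Signalling lists held few calls. BMPR2, a BMP receptor, fell in the group-only fit (-0.65 ± 0.09 SE, adjusted p = 0.0487). It did not pass with normexp (-0.45, adjusted p = 0.154), the series matrix (-0.46), quantile normalization, median centring or the robust model. TGFBR1, a TGF-beta receptor, rose with the block (0.55 ± 0.08 SE, adjusted p = 0.0165; 0.24 with normexp, not past the threshold), while the 30 genes of that list had a mean of 0.00 (camera adjusted p = 0.963). EPHA2 among 19 ERK output genes fell with the block (-0.35, adjusted p = 0.0254; -0.25 with normexp, not past the threshold), with SPRED1 at 0.37 and ETV1 at 0.36 not past the threshold; the list mean was -0.04 (0.508). USP18 among 21 interferon-stimulated genes fell with the block (-0.47, adjusted p = 0.0175), with IFIT1 at 0.49 not past it and a list mean of 0.02 (0.764). Of 20 YAP/TEAD targets, F3 (0.41, adjusted p = 0.0493; not past the threshold with median centring or the mean of probes) and NT5E (0.38, 0.0467) rose with the block, and the list mean was 0.01, from 0.16 on slide 1 and -0.15 on slide 2 (0.848). No member passed in either fit among 38 growth factor receptors and RAS-MAPK-AKT components (mean 0.01, camera adjusted p = 0.951; SOS2 0.27), 22 NF-kB targets (-0.03, 0.497; CXCL8 0.95 with 2.30 on slide 1 and -0.41 on slide 2, CXCL1 -0.34) or 29 WNT genes (-0.05, 0.518; LGR5 -0.43, LEF1 -0.38). CXCL8 and LGR5 were each well above background on 6 of 8 arrays.

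In the stress and RNA lists, the block added the chaperone HSPA5 (0.36, adjusted p = 0.0393) as a rise among 30 unfolded protein response and ATF4 genes (list mean 0.08, camera adjusted p = 0.299; SESN2 fell with the block, and SEL1L, 0.49, did not pass) and the autophagy kinase ULK1 (-0.61, adjusted p = 0.0225) as a fall among 31 autophagy and lysosome genes (-0.05, 0.401; CTSD -0.31 did not pass). Of 21 genes of the microRNA machinery, including the host gene (mean 0.02, adjusted p = 0.798), the exonuclease XRN1 (0.60 ± 0.09 SE, adjusted p = 0.0163) and the deadenylase subunit CNOT7 (0.38, 0.0359) rose with the block, and PRKRA stood at 0.40. A second probe of CNOT7 gave 0.15, and with normexp CNOT7 was at 0.14 and did not pass (adjusted p = 0.349). KDM6B was the 1 gene of 27 chromatin and DNA methylation enzymes past the threshold (list mean 0.02, adjusted p = 0.976). Heat shock and NRF2 targets had a mean of 0.01 over 24 genes (0.690), with NQO1 at -0.38 and BAG3 at 0.35.

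In structural lists CLDN1, a tight junction claudin, rose with the block (0.59, adjusted p = 0.0393) among 23 epithelial genes (list mean -0.02, camera adjusted p = 0.764; CLDN6 -0.49 did not pass), and the 19 mesenchymal and matrix genes had a mean of -0.03 (0.798; TAGLN -0.51, COL5A1 0.37). Cytosolic ribosomal proteins had a mean of 0.06 over 39 genes (0.344; RPS23 0.67 with a control SD of 1.16, RPS3 0.19). They passed as higher with array weights (0.12, camera adjusted p = 0.00278) and without mimic replicate 4 or control replicate 7. The 16 reference genes had a mean of 0.08 (0.344; IPO8 0.32, HPRT1 0.31). Of these, 15 had a positive and 1 a negative log2 fold change, with means of 0.11 on slide 1 and 0.05 on slide 2. Their list mean gave an exact permutation p of 0.171, and 0.0556 within slides, the smallest possible there. Fry gave an adjusted p of 0.394 without and 0.139 with the block. Markers of other cell types showed no called shift: the means were -0.11 over 4 endothelial genes (0.690; CLDN5 -0.35, ESAM -0.18), -0.02 over 7 immune genes (0.798; CD3D -0.18), 0.06 over 6 fibroblast and stellate genes (0.848; PDGFRB 0.56, COL1A2 -0.23; adjusted over the list alone 1 rose) and -0.06 over 10 cholangiocyte genes (0.764; MUC1 -0.39, TFF3 0.35). COL5A1 was well above background on 6 of 8 arrays, CLDN5 on 5, and ESAM and MUC1 on 7. Among genes past the threshold in neither fit, other probes gave other values, at least 1 of them over 1.5 times smaller, for MKI67 (-0.14 to -0.10), RRM2B (0.16), XIAP (0.04), ETV1 (0.03 to 0.31), SEL1L (0.04 to 0.25), RPS23 (0.10) and TFF3 (0.18 to 0.34). Mean and median differed in sign for p53 targets, growth factor receptors, epithelial, mesenchymal, YAP/TEAD, heat shock, microRNA machinery and fibroblast lists, and camera's direction opposed the mean for oncofetal, TGF-beta and chromatin lists in the group-only fit and for oncofetal, YAP/TEAD and microRNA machinery lists with the block, all of them not past the threshold. With an estimated correlation no list passed in either fit. Adjusted over the list alone, 3 members of the microRNA machinery list rose in the group-only fit, 1 member each of the glycolysis, hypoxia, p53, unfolded protein response, autophagy, TGF-beta and chromatin lists fell, and 0 passed in the remaining lists not given above.

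**Figure D4:**
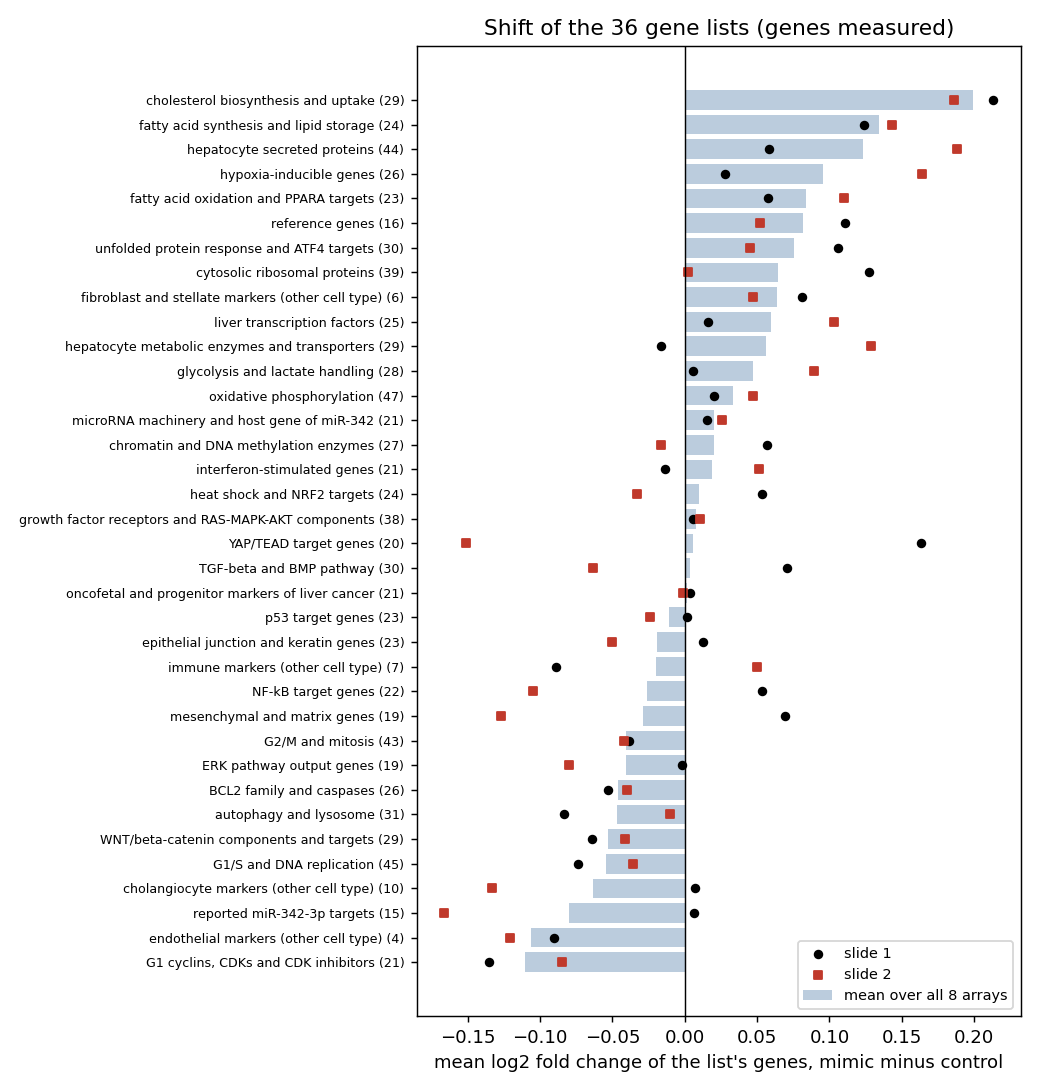
Mean log2 fold change, mimic minus control (x axis), of the genes of each of the 36 fixed lists (y axis, with the number of genes measured); bars are all 8 arrays, circles slide 1 and squares slide 2. Cholesterol biosynthesis and uptake has the highest mean (0.20), with both slides close to it, while lists such as YAP/TEAD targets have slide values of opposite sign.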

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

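Of the tests in this part, those of the cholesterol list against a difference between slides and of the blocked calls against noise of single slides were chosen only after the result was seen. The same holds for fits with slide as a block beyond the first, other than those of the slide-balanced splits. In the probe-by-probe test of the slide difference, the denominator was changed after a first value had been seen, from 1 probe's own correlation to the geometric mean over both probes, with the same verdict.

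In 8 of 328 checked sets of 4 values, 1 array lay far from the other 3 (a gap to the nearest above Dixon's critical share of the whole range). Chance alone gives about 16.4 such sets. ADH4 in control replicate 1 was at -2.92 against a mean of -6.30 in the other controls (gap 0.860 of the range). CLDN5 in control replicate 1 was at -5.75 against -5.30 (0.955), and GLCE in the same array was at -3.31 against -3.02 (0.899). SLC16A1 in control replicate 7 was at 0.50 against 0.29 (0.870). BAG3 in mimic replicate 10 was at -0.64 against -0.83 (0.833), EVL in mimic replicate 3 at 1.18 against 0.98 (0.832) and XRN1 in mimic replicate 9 at -0.98 against -1.17 (0.896). The mean of the oxidative phosphorylation list in control replicate 8 was 4.49 against 4.61 (0.844). Among 3641 tested probes without a gene symbol, 1 passed the threshold, probe A_33_P3234457 (log2 fold change -0.77, adjusted p = 0.0475).

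The first pattern was the separation of the arrays by slide. Dim probes near background were argued against as its whole cause: the share of slide-different genes among the 3494 brightest genes was 0.820 of that among the 3494 dimmest (42.8% against 52.2%). A hybridization difference acting probe by probe had the value it needs: over 3395 genes, the slide difference correlated at 0.219 between 2 probes of a gene and at 0.811 for the same probe between groups, a ratio of 0.270 (95% bootstrap interval 0.223 to 0.319). The mimic effect, set between slides, correlated at 0.191 between 2 probes and at 0.362 for the same probe, a ratio of 0.528. Probes of a gene thus agreed only in part for the mimic effect too. A difference between cultures of the 2 slides stays open and was not tested, since the labels name none.

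The second pattern was the higher cholesterol list. A shift depending on brightness was argued against, since the list's mean lay at percentile 100 of 10000 brightness-matched random lists, the highest of which was 0.126. The smaller within-slide shift of 0.186 decides nothing about a difference between slides, since each slide held both groups equally. A linear gradient over array positions was argued against (mean step within a group -0.170 of the shift; -0.03 ± 0.02 SE). A position effect that is not linear could not be told apart from the mimic, because both mimic arrays held positions 3 and 4 on each slide. An effect of the mimic may account for the shift, as a hypothesis. For lists, 24 of 35 splits of the 8 arrays gave at least as many calls (real 2, highest other 7), so chance was not excluded for their number. With slide as a block, 7 of the 18 slide-balanced splits, the real one among them, gave at least as many (real 3, highest other 8). Chance was thus not excluded for that number either, and 18 splits could in any case give no share under 0.05.

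The third pattern was the genes called with slide as a block. Of 500 genes chosen on slide 1, 84.8% changed in the same direction on slide 2. These genes were read on the same arrays and are not independent, so the share does not decide about noise of single slides. A linear gradient over positions was argued against by a signed step of -0.0675 of the change between groups on slide 2. For these genes too, a position effect that is not linear could not be told apart from the mimic. The mimic arrays held the same positions on each slide, apart from those of the controls. Such an effect could therefore also give the same direction on each slide. The 18 slide-balanced splits were too few for a share under 0.05, with 1 giving as many (real 447, highest other 2). Without the block 2 of 35 splits gave as many genes as the real one (21), so chance was not excluded; the other was the split by slide, with 5894 genes, which points to a structure of the samples, and the highest besides it was 1.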

How the results depend on the processing

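The fits that combine slide as a block with another setting, and those that keep probes without a gene symbol, were chosen only after the result was seen. No paired analysis was possible because the groups share no replicate number. The seed-site tests were not run. No value past the threshold in either setting changed sign; sign changes between values past it in neither were counted as the same result.

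In the group-only fit (6 genes higher, 15 lower; 2 lists higher, 0 lower), normexp, quantile normalization, median centring, brighter probes, outlier spots kept, mean of probes, the robust variance model and a 1.5-fold minimum kept both gene counts within 1.5 times. Without a filter on dim probes 0 were higher and 0 lower, and likewise at an adjusted p under 0.01 and with treat against 1.2-fold. Array quality weights gave 10 higher, series matrix values 3, a log2 fold change of at least 1 gave 1 and 3, probes without a symbol kept 1 higher, slide 1 alone 1 lower, slide 2 alone 1 and 0, and slide as a block 224 and 223. Leaving out an array gave 0 to 1 higher and 0 to 1 lower, 1 of each without control replicate 8 and 0 otherwise. Fewer arrays or more genes tested may account for part of these losses, and their cause was not tested.

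Lists higher were 4 with weights (hypoxia-inducible and ribosomal genes among them), 1 on slide 1 alone, 0 with an estimated correlation, 1 with fry and 1 to 4 without an array (1 without mimic replicate 10). Lists lower were 2 without the filter and 2 with the mean of probes (reported targets and G1 cyclins in both), 2 with weights (G2/M and G1 cyclins) and 0 to 3 without an array (these 3 lists without mimic replicate 4, and G1 cyclins without control replicate 8). The cholesterol mean did not pass with an estimated correlation or fry (0.199 in both) and passed without any array (0.173 to 0.236). Fatty acid synthesis did not pass with weights (0.135), on slide 1 alone (0.124), with an estimated correlation (0.134) or without mimic replicate 10 (range 0.122 to 0.143). Reported targets passed without the filter (-0.0548), with the mean of probes (-0.100) and without mimic replicate 4 (range -0.106 to -0.0399). Hepatocyte secreted proteins passed with normexp (0.102), no filter (0.131), mean of probes (0.113), the robust model (0.123), weights (0.211), the block (0.123), slide 2 alone (0.188) and without mimic replicates 3 or 4 or control replicate 7 (range 0.0523 to 0.193). The cause was not tested.

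With slide as a block (224 and 223 genes; 3 lists higher, 0 lower), counts were 11 and 21 without the filter, 355 higher with probes well above background on all arrays, 382 and 343 with the robust model, 12 and 20 at an adjusted p under 0.01, 144 and 139 with unnamed probes kept, and 34 to 245 and 54 to 219 without an array (lowest without mimic replicates 9 and 4). Lists lower were 1 with quantile normalization, 1 without the filter and 1 with the series matrix (G1/S in each), 1 with the mean of probes (G1 cyclins) and 0 to 2 without an array (G1/S or G1 cyclins); lists higher were 0 with an estimated correlation and 2 to 3 without an array. With an estimated correlation cholesterol (0.199) and fatty acid synthesis (0.134) did not pass. Hepatocyte secreted proteins did not pass with quantile normalization (0.103), an estimated correlation or fry (0.123) or without mimic replicates 3 or 9 or control replicates 7 or 8 (range 0.0831 to 0.162). Without an array, the cholesterol mean was 0.185 to 0.220, fatty acid synthesis 0.123 to 0.148 and targets -0.102 to -0.0414.

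For 123 named genes, of 2565 values 2269 were on the same side of the threshold and in the same direction, 219 lost and 44 gained the call and 33 changed sign below it; with the block these were 1878, 263, 43 and 15 of 2199. For 36 lists, of 828 values 718 were the same, 6 lost and 24 gained the call and 80 changed sign below it; with the block 655, 9, 10 and 46 of 720. Signal over background limited 933 of the 13974 genes, which were not well above it on all 8 arrays.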

Other observations

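The tests of INSIG1 and of the metallothionein group were chosen only after the result was seen; the test of SLC30A1 was written before its value was seen. For the metallothionein group and for SLC30A1, the rule for excluding the explanation was loosened after the p was seen, because the difference between slides widens the spread in a test without slides and a p that misses the threshold excludes nothing.

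Metallothionein genes encode small zinc-binding proteins and are on none of the fixed lists. All 9 measured members had a negative log2 fold change, also with normexp, quantile normalization, median centring and the series matrix, and 6 of the 9 passed with slide as a block: MT1A, MT1B, MT1E, MT1F, MT1G and MT1H. MT1H stood at -0.63 ± 0.08 SE (adjusted p = 0.0123; -0.55 on slide 1 and -0.70 on slide 2) and MT1E at -0.52 ± 0.08 SE (adjusted p = 0.0184), while MT1X (-0.44, adjusted p = 0.0549), MT2A (-0.34, 0.116) and MT1M (-0.31, 0.291) did not pass. None passed in the group-only fit. Probes of these near-identical genes may read each other's transcripts, so the 9 values are not independent. The group's mean was 4.79 ± 0.27 in control and 4.32 ± 0.38 in mimic arrays (SD, n = 4; -0.35 on slide 1 and -0.59 on slide 2), with p = 0.114 in an exact permutation test, two-sided, and 0.0556 within slides, the smallest possible there, so the test left it open.

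Lower activity of the zinc sensor MTF1 may be proposed as a hypothesis, and it requires SLC30A1, a zinc exporter gene it also activates, to fall. SLC30A1 stood at -0.16 (-0.05 on slide 1 and -0.27 on slide 2) with p = 0.486 in an exact permutation test, two-sided, and 0.167 within slides, where 0.0556 is the smallest possible. With slide as a block its standard error was 0.08 and its adjusted p 0.292. The required fall was not shown, and these arrays do not exclude it, so the hypothesis stays open. SLC30A2, a zinc transporter of vesicles, was among the genes lower with slide as a block.

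INSIG1 had the lowest log2 fold change of the 29 cholesterol genes and was picked for that. Its signal minus the mean of the other 28 members was -0.90 ± 0.21 in control and -1.70 ± 0.13 in mimic arrays (SD, n = 4), a difference of -0.80. An exact permutation test, two-sided, of INSIG1 alone gave p = 0.0286, which restates the choice of the gene. With the most deviating of the 29 members taken in each of the 70 assignments, the exact permutation p was 0.0857 (0.0556 within slides, the smallest possible), so whether INSIG1 departs from the list stays open. INSIG1 retains the SREBP complex, and a hypothesis is that lower INSIG1 may accompany the higher mean of the list; the seed-site test that bears on a direct effect of the mimic was not run.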
